A study of Homo sapiens with 6 samples.

How the data were processed

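RNA was measured in 6 libraries of IMR90 fibroblasts expressing ER-RAS, 3 after 30 h and 3 after 72 h of 100 nM 4OHT. The sample titles give the times as 1.5 days and 3 days, while the labels' protocols give 30 h and 72 h. The shorter time differs between these sources, and the hours are used here because the column names of the deposited table also carry them. Per the labels' protocols, cells were lysed in TRIzol, RNA was cleaned on RNeasy columns, and libraries were made with the KAPA mRNA HyperPrep kit. The labels do not say whether the replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical. Replicates of a group differed by more than sampling noise in a chi-square comparison of their reads (3.34 to 16.3 per degree of freedom, against 110 to 161 between groups), so each was counted as a sample of its own.

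Per the submitters' processing notes, reads were trimmed with Trimmomatic 0.35, aligned with STAR 2.5.1b to GRCh38 (hg38) and compared with DESeq2 1.18.1. The read counter, the gene annotation and the strand setting are not given in the sources used here. The deposited table holds, for 58219 genes, 1 signal value per library, a read count that the authors divided by a size factor of that library. In each library 100% of the values were whole multiples, within 0.01, of its smallest value above 0, which gave back the whole reads and totals of 13221152 to 15703544 per library. The authors' size factors, rebuilt from those values, ran from 0.948 to 1.15. Per the file headers the table also holds the authors' log2 fold change with its standard error, a score (the Wald statistic of DESeq2), and a p-value with its adjusted form. These columns were used only where the authors' deposited table is named and as an alternative. The number of other columns of per-sample values left out was 0. PCR duplicates cannot be told from separate molecules in such counts, so floors cover counting error only.

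Genes with at least 10 normalised counts in at least 3 libraries were tested (13315 genes), and 31393 genes had no read in any library. Values were put on a log2 scale after adding 1 and compared between 72 h and 30 h with limma 3.58.1 (trend and robust options) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. Log2 fold changes are given with limma's standard error, folds are those of the fit, and positive values are higher at 72 h. The replicate letters were not used as pairs, because after removal of group means the correlation of the libraries of 1 letter was 0.00696 for A, 0.172 for B and 0.185 for C, not above 0.1 for each. With 3 libraries per group each call was repeated without each library in turn. Counts of all genes past the filter were also simulated from the real means and dispersions, with 200 genes changed, and 13150 genes were tested. The same steps recovered 59.7% of genes changed 1.5-fold, 82.1% of those changed 2-fold and 97.0% of those changed 4-fold. Far fewer genes changed there than were called in the data, and genes were drawn independently, without a shift of letter C. These rates therefore need not hold for the real comparison. Of 167 simulated calls, 8 were genes that had not been changed.

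The lists of genes (23 lists with 696 members, 633 of them tested), the rule for named genes, the tests and most alternatives were fixed before the data were examined. Lists were compared with all other tested genes by camera from limma, with a preset inter-gene correlation of 0.01 and adjustment over the 23 lists, again with an estimated correlation, and by fry. Counts adjusted over the list alone use the members' p-values only. The rule named the 8 largest rises and the 8 largest falls among genes past the threshold (clone names, LINC and antisense symbols left out) with a mean of at least 50 in the higher group and no overlap between groups. It also named up to 4 called members of each list with the largest change and a mean of at least 50, and, whatever their value, HRAS, CDKN1A, CDKN2A, CDKN2B, LMNB1, HMGA2, PML, IL6, CXCL8, IL1A, IL1B, MKI67, CCNA2, DUSP6 and SPRY4. Some genes that the rule names are not reported here. Members named outside this rule, because a count was small or, for NRAS and ESR1, beside HRAS, were chosen after the data were seen. Symbols are those of the deposited table, in which CTGF stands for CCN2.

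Coordinates are from the deposited table, on GRCh38. Of the tested gene identifiers 99.8% were found in GENCODE 29 without their version and 91.17% with it, and those 12139 had the same coordinates. GENCODE 29 was used for gene overlaps, lengths and GC content. Exons of CCNA2, DPP4, DUSP6, FADS1, FTH1, GINS2, IER3, IL6, ITGA6, KIF20A, MVK, PDE7B, POLR1C, RASA1, SOD2, SQSTM1, TAGLN, THBS1, TNFRSF10B and TSR1 overlap another gene on the opposite strand, and those of PFKFB4 and TM7SF2 one on the same strand, so part of their reads is uncertain. Reads of genes with close copies, such as CXCL1, CXCL2 and CXCL3, SERPINB3 and SERPINB4, ACTA2 and ACTG2, FTH1 and its pseudogenes, or mitochondrial genes and their nuclear copies, may be split among them.

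The alternatives were a block for the replicate letter, TMM scaling, quantile normalisation, no filter on low values, a filter at 50, pseudocounts of 0.5 and 10, a log2 fold change of at least 1, an adjusted p under 0.01, each library left out, edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads, and the authors' DESeq2 columns. Leaving out both libraries of letter C was added after the data were seen. Sequence reads were not used here.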

Results

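Polyadenylated RNA was sequenced from IMR90 cells, a line of normal diploid fibroblasts from human lung, that express ER-RAS. ER-RAS is an oncogenic RAS protein fused to a part of the oestrogen receptor, and it becomes active when 4-hydroxytamoxifen (4OHT) is added to the medium. The cells received 100 nM 4OHT for 30 h (3 libraries, named in the labels as uncommitted controls) or for 72 h (3 libraries, named as committed). The depth was 13221152 to 15703544 reads assigned to genes per library. On the first principal component, which held 81.3% of the variance, the 3 libraries of 30 h lay apart from the 3 of 72 h. Both libraries of letter C lay apart from the others on the second, which held 7.0%. The share of reads from mitochondrial genes was 3.56% to 4.06% at 30 h and 4.23% to 4.83% at 72 h, and the 20 most abundant genes took 9.73% to 10.0% and 10.8% to 12.7% of the reads.

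The comparison of 72 h with 30 h asks which transcripts differ between fibroblasts labelled committed to senescence and uncommitted ones, both under RAS signalling. Commitment and time under RAS signalling differ together between these groups. The samples include no untreated group and no uncommitted group at 72 h. The changes below therefore cannot be assigned to commitment rather than to time. At 72 h, genes for inflammatory chemokines, cytokines and their NF-kB regulators were higher, as were genes of glycolysis and the hypoxia response. Genes for DNA replication, mitosis, recombination repair, the extracellular matrix and the contractile cytoskeleton were lower. These list calls rest on camera's preset correlation, and 0 of the 8 lists called held with an estimated correlation (adjusted p = 0.423 to 0.659). Of 13315 genes tested with limma, 3144 rose and 3328 fell at a Benjamini-Hochberg adjusted p under 0.05. The change was at least 2-fold for 686 of the genes that rose and 892 of those that fell. In the authors' deposited table, which gives an adjusted p for 17065 genes, 2627 were higher and 2883 lower at 72 h. Of 11920 protein-coding genes tested, 2930 rose and 3170 fell, and of 905 long non-coding genes tested, 155 rose and 111 fell.

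**Figure D1:**
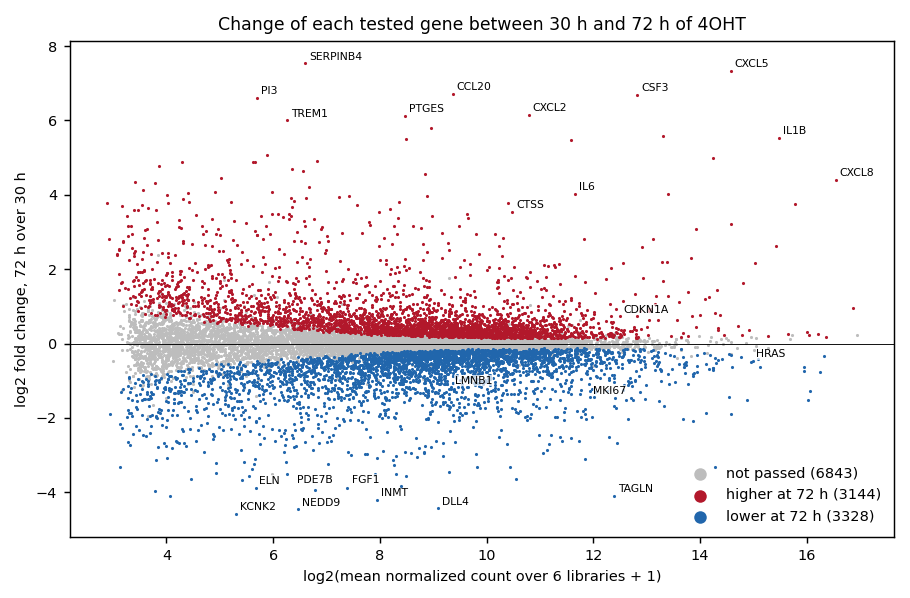
Each point is 1 of 13315 tested genes, with its mean normalised count over the 6 libraries on the x axis (log2 of the mean + 1) and its log2 fold change, 72 h over 30 h, on the y axis. Red points are the 3144 genes that rose and blue points the 3328 that fell, grey points did not pass, and the points of SERPINB4 and PI3, with 0 reads at 30 h, depend on the pseudocount.

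The 8 largest rises by the naming rule were those of SERPINB4, CXCL5, CCL20, CSF3, PI3, CXCL2, PTGES and TREM1. CXCL5, a neutrophil chemokine (ENSG00000163735.6, chromosome 4, 73995642 to 73998779), went from 313 ± 195 to 48706 ± 25439 normalised counts (mean ± SD, n = 3 per group), a log2 fold change of 7.34 ± 0.57 (SE) with adjusted p = 0.000371. CCL20, a chemokine for lymphocytes and dendritic cells (chromosome 2, 227813842 to 227817564), went from 12.6 ± 6.29 to 1309.7 ± 23.4. CSF3, the granulocyte growth factor G-CSF (chromosome 17, 40015361 to 40017813), went from 146 ± 52.9 to 14378 ± 816. CXCL2 rose 71.4-fold and PTGES, a prostaglandin E synthase, 69.6-fold. SERPINB4, a protease inhibitor of squamous epithelia (chromosome 18, 63637259 to 63644298), had 0 reads at 30 h and 192 ± 66.0 normalised counts at 72 h, at least 189-fold higher than a floor of 3 reads over the group. PI3, the elastase inhibitor elafin, also had 0 reads at 30 h and was at least 100.1-fold higher by the same floor, at 102 ± 42.9. TREM1, a receptor of myeloid cells that amplifies inflammation, had 0, 0 and 6 reads in the 3 libraries of 30 h and 149 ± 119 normalised counts at 72 h. Its fitted rise of 64.0-fold (adjusted p = 0.00323) was 42.0-fold without 72 h replicate C. Without 30 h replicate C the other libraries of 30 h had 0 reads, so the rise was then at least 100.1-fold by a floor of 3 reads over the group, with no upper limit.

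The 8 largest falls were those of KCNK2, NEDD9, DLL4, INMT, TAGLN, PDE7B, FGF1 and ELN. KCNK2, a potassium channel (chromosome 1, 215005775 to 215237093), fell 24.0-fold to 2.24 ± 1.06 normalised counts from 74.7 ± 15.5. NEDD9, a scaffold protein of focal adhesions, fell 22.0-fold from 169 ± 17.7 to 6.97 ± 2.44. DLL4, a ligand of Notch receptors (chromosome 15, 40929340 to 40939072), fell from 1046 ± 259 to 47.9 ± 12.8, a log2 fold change of -4.42 ± 0.24 (SE) with adjusted p = 1.7e-05. TAGLN, the actin-binding protein transgelin (chromosome 11, 117199321 to 117204782), fell from 10110.5 ± 1710.1 to 624 ± 263. INMT, a methyltransferase, fell 18.4-fold, which was 10.7-fold without 72 h replicate C. PDE7B, a cyclic AMP phosphodiesterase, and FGF1, a fibroblast growth factor, fell 15.5-fold and 14.8-fold. ELN, the gene of elastin, fell 14.7-fold, which was 9.48-fold without 30 h replicate C, the library with 177 of its reads against 49 and 51 in the others of 30 h. At 72 h KCNK2 had 3, 3 and 1 reads and ELN 4, 3 and 7, so the added 1 shrank their fitted folds and bears on the order. By edgeR their log2 fold changes were -4.97 and -4.34, against -4.58 and -3.87 by limma.

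HRAS and NRAS fell between 30 h and 72 h. HRAS (chromosome 11, 532242 to 537287) went from 37555 ± 416 to 27310.1 ± 2784 normalised counts, a log2 fold change of -0.46 ± 0.0744 (SE) with adjusted p = 0.000702. NRAS, a member of the senescence regulator list, had a log2 fold change of -0.45 with adjusted p = 0.000113. Counts per gene do not separate reads of the cell's own HRAS from any reads of ER-RAS that map to it, and both groups carry the construct.

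Transcripts of the senescence-associated secretory phenotype (SASP), the cytokines, chemokines, growth factors and proteases released by senescent cells, rose at 72 h. Of 41 members tested, 30 rose, 5 fell and 6 did not pass, and 31 rose and 5 fell when adjusted over the list alone. The median log2 fold change was 2.02. CXCL8, the chemokine interleukin 8, went from 9402 ± 4796 to 182123 ± 19084 normalised counts and was 21.1-fold higher (adjusted p = 0.000598). IL1B, a cytokine that drives other SASP genes, went from 2048 ± 852 to 89529 ± 16317, IL1A from 135 ± 52.4 to 1458 ± 280.2 and IL6 from 400.4 ± 186 to 6082 ± 1065, with log2 fold changes of 5.53, 3.48 and 4.02. The 5 members that fell, named after their values were seen, were PLAT and PLAU, which encode plasminogen activators, TNFRSF11B, a decoy receptor for the bone factor RANKL, IGFBP7, a binding protein of insulin-like growth factors, and HGF, hepatocyte growth factor. Their log2 fold changes were -2.07, -0.34, -1.67, -0.67 and -0.58. The list was higher by camera, a test of a list against all other genes, with adjusted p = 2.66e-10, and with adjusted p = 0.504 with an estimated correlation. CXCL2 shares sequence with CXCL1 and CXCL3, so the split of reads among them is uncertain.

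Regulators and targets of NF-kB and C/EBP, the transcription factors of SASP genes, rose as a group. Of 26 members tested, 20 rose, 1 fell and 5 did not pass, with 21 rising and 1 falling when adjusted over the list alone, and the median log2 fold change was 0.98. PTGS2, the inducible cyclooxygenase, went from 1266 ± 753 to 37411 ± 11387 normalised counts, and SOD2, the mitochondrial superoxide dismutase, from 3296 ± 412 to 27582 ± 953. TRAF1, a signalling adaptor of tumour necrosis factor receptors, rose 7.88-fold and IRAK3, a negative regulator of interleukin 1 signalling, 7.73-fold. The member that fell, named after its value was seen, was IRAK1, a kinase of the same interleukin 1 pathway, at a log2 fold change of -0.31. Camera gave adjusted p = 5.35e-09, and adjusted p = 0.423 with an estimated correlation. Exons of SOD2 overlap WTAP on the opposite strand, and strand use in the authors' counting is not given in the sources used here.

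Genes of the cell cycle fell together. Of 48 mitosis and G2/M genes tested, 46 fell, 0 rose and 2 did not pass, with 47 falling when adjusted over the list alone, and the median log2 fold change was -1.44. MKI67, the proliferation marker Ki-67, fell from 5669 ± 570.1 to 2156 ± 657 normalised counts and CCNA2, the gene of cyclin A2, from 1306 ± 163 to 505 ± 137. KIF20A, a kinesin of cytokinesis, fell 4.31-fold, NEK2, a centrosomal kinase, 3.97-fold, NUF2, a kinetochore protein, 3.65-fold and ASPM, a spindle pole protein, 3.49-fold. The 2 members that did not pass, named after their values were seen, were CDK1 and CKAP2L, with log2 fold changes of -0.84 and -0.46 and adjusted p = 0.0738 and 0.331. Exons of KIF20A overlap BRD8 and CDC23, and those of CCNA2 overlap EXOSC9, on the opposite strand. The list was lower by camera with adjusted p = 7.91e-14, and adjusted p = 0.515 with an estimated correlation.

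Among 46 DNA replication genes and E2F targets tested, 38 fell, 1 rose and 7 did not pass, with 42 falling and 1 rising when adjusted over the list alone. The median log2 fold change was -0.84. TK1, the thymidine kinase of S phase, fell from 666 ± 127 to 214 ± 68.8 normalised counts, E2F8, a repressor of E2F targets, from 61.2 ± 13.7 to 17.8 ± 5.49, and POLE2, a subunit of DNA polymerase epsilon, 2.90-fold. GINS2, a subunit of the replicative helicase, fell 2.38-fold. CCNE1, the gene of cyclin E1 and the member that rose, was named after its value was seen, with a log2 fold change of 0.69. Of 22 genes of homologous recombination and the Fanconi pathway, 20 fell, 1 rose and 1 did not pass, the same counts as when adjusted over the list alone. FANCD2, the central protein of the Fanconi pathway, fell from 399 ± 46.7 to 113 ± 46.5 normalised counts, the helicase gene BRIP1 2.80-fold and BARD1, the partner of BRCA1, 2.55-fold. PALB2, which links BRCA1 to BRCA2, rose with a log2 fold change of 0.21, and RBBP8, a DNA end resection factor, had 0.00 with adjusted p = 0.99, both named after their values were seen. Camera gave adjusted p = 1.15e-09 for the replication list and 5.64e-06 for the repair list. For each list it gave adjusted p = 0.515 with an estimated correlation.

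Genes of the extracellular matrix and the contractile cytoskeleton fell. Of 34 members tested, 27 fell, 0 rose and 7 did not pass, with 29 falling when adjusted over the list alone, and the median log2 fold change was -1.51. THBS1, the adhesive glycoprotein thrombospondin 1, fell from 35871 ± 3769 to 3805 ± 1456 normalised counts. ACTG2, a smooth muscle actin, fell from 2514 ± 547 to 253 ± 62.9, although some reads may be split between ACTG2 and its close copy ACTA2. TAGLN and ELN, given above, were the members with the largest falls, and exons of TAGLN overlap PCSK7 on the opposite strand. The list was lower by camera with adjusted p = 6.31e-14, and adjusted p = 0.423 with an estimated correlation.

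Genes of glycolysis and the hypoxia response rose. Of 25 members tested, 20 rose, 1 fell and 4 did not pass, with 20 rising and 3 falling when adjusted over the list alone, and the median log2 fold change was 0.76. ALDOC, an aldolase, went from 64.5 ± 11.7 to 471 ± 108 normalised counts, BNIP3, a mitophagy receptor, from 992 ± 79.6 to 3456 ± 492, and ENO2, an enolase, from 789.8 ± 44.2 to 2678 ± 245. PFKFB4, which makes an activator of glycolysis, rose 2.36-fold and shares exonic sequence with UCN2 on the same strand. The member that fell, named after its value was seen, was SLC2A3, a glucose transporter, at a log2 fold change of -0.82. The list was higher by camera with adjusted p = 7e-08, and adjusted p = 0.423 with an estimated correlation.

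Of the 13 messenger RNAs encoded by mitochondrial DNA, 9 rose, 0 fell and 4 did not pass, also when adjusted over the list alone, with a median log2 fold change of 0.25. MT-ND3, a subunit of respiratory complex I, went from 5863 ± 404 to 8015 ± 607 normalised counts, and MT-ND2 from 17712 ± 1415 to 23869 ± 1588. Camera gave adjusted p = 0.0119, and adjusted p = 0.659 with an estimated correlation. The call was lost without 72 h replicate A, at adjusted p = 0.056, and with quantile normalisation, at 0.0936, the highest of a range from 0.000212 over the alternatives.

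The self-contained test fry, which asks whether a list's own genes move on balance one way, gave 17 of 23 lists an adjusted p under 0.05.

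**Figure D2:**
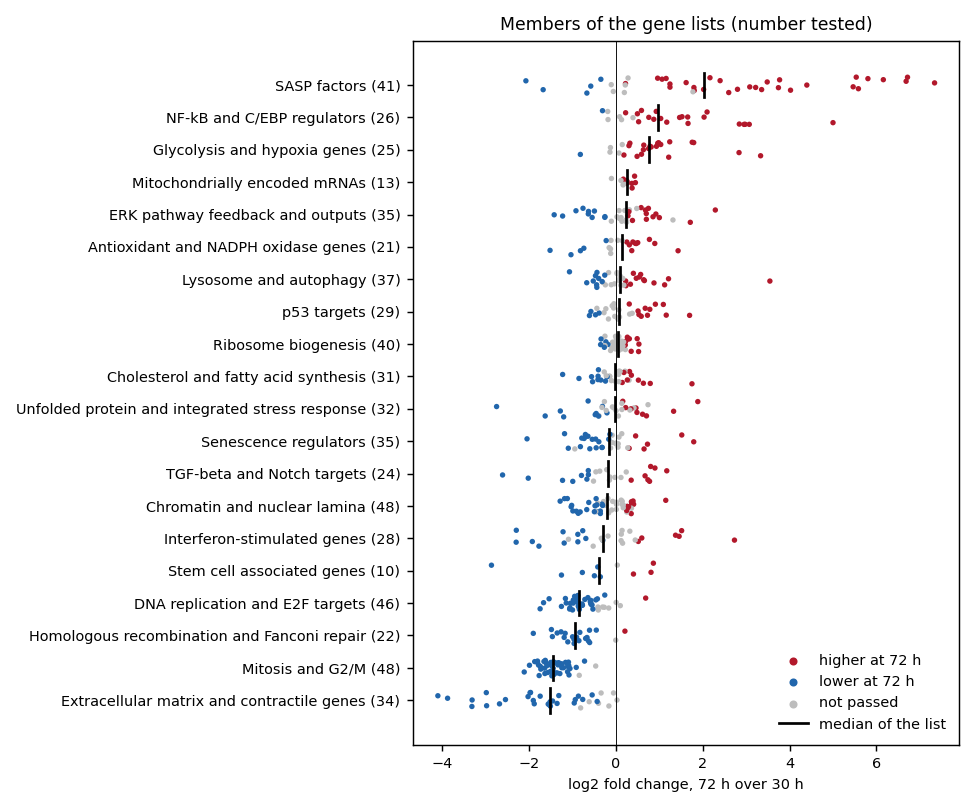
Each point is a tested gene at its log2 fold change, 72 h over 30 h (x axis), in the row of its list, for the lists with at least 10 tested genes (number in brackets). Red and blue points rose and fell, grey points did not pass, and the black bars are the list medians, from 2.02 for SASP factors to -1.51 for the extracellular matrix and contractile genes.

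The regulators of senescence went in both directions. Of 35 tested, 6 rose, 18 fell and 11 did not pass, with 6 rising and 19 falling when adjusted over the list alone. CDKN1A, the gene of the cell cycle inhibitor p21, rose from 4295 ± 114 to 7206 ± 1367 normalised counts with adjusted p = 0.00346. CDKN2A, the gene of p16 and ARF, fell from 264 ± 35.6 to 175 ± 31.3 with adjusted p = 0.00899, and its neighbour CDKN2B, the gene of p15, from 1111 ± 273 to 674 ± 89.5 with adjusted p = 0.0224. The call for CDKN2B was lost without 72 h replicate B, at adjusted p = 0.0684, and without 72 h replicate C, at 0.0807 (4.8e-05 to 0.0807 over the alternatives). CDKN2C, the gene of the inhibitor p18, fell 4.13-fold, while DPP4, a surface peptidase, rose 3.47-fold and SOCS3, a suppressor of cytokine signalling, 2.86-fold. PML, the gene of the nuclear body protein, had 332 ± 19.2 at 30 h and 349 ± 67.0 at 72 h with adjusted p = 0.764. The camera adjusted p of the list was 0.0639, and 0.0458 without 72 h replicate A (0.00648 to 0.188 over the alternatives).

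Among 48 genes of chromatin and the nuclear lamina, 10 rose, 20 fell and 18 did not pass, the same counts as when adjusted over the list alone. LMNB1, the gene of lamin B1, fell from 896 ± 78.9 to 395 ± 46.2 normalised counts (log2 fold change -1.18 ± 0.0970 SE, adjusted p = 1.24e-05). HMGB2, a chromatin protein, fell 2.43-fold, while KDM6B, a demethylase of histone H3, rose from 469.8 ± 58.9 to 1039.7 ± 74.4. HMGA2, a chromatin protein of senescent foci, had 16282 ± 2110.5 at 30 h and 15266 ± 2146 at 72 h with adjusted p = 0.577. For this list the camera adjusted p was 0.0639, and 0.0458 without 72 h replicate A (0.00457 to 0.11 over the alternatives).

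Of 29 targets of p53 tested, 11 rose, 4 fell and 14 did not pass, the same counts as when adjusted over the list alone. GDF15, a stress cytokine, rose from 555 ± 128 to 1803 ± 396 normalised counts, TNFRSF10B, a death receptor, 2.13-fold and SUSD6 1.88-fold. BTG2, an antiproliferative gene, rose 2.24-fold with adjusted p = 0.0182, a call lost without 30 h replicate A (adjusted p = 0.0678), 72 h replicate A (0.0731, the highest from 2.57e-05 over the alternatives) or 72 h replicate B (0.065). The 4 members that fell, named after their values were seen, were FAS, a death receptor, GADD45A, a stress response gene, POLH, a translesion polymerase, and TP53I3, an oxidoreductase. The p53 list had a camera adjusted p of 0.176, and 0.0174 without 72 h replicate C (0.0174 to 0.379 over the alternatives).

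Outputs and feedback regulators of the ERK pathway, which acts downstream of RAS, were divided. Of 35 tested, 13 rose, 10 fell and 12 did not pass, with 16 rising and 10 falling when adjusted over the list alone (camera adjusted p = 0.195). DUSP6, a phosphatase of ERK, rose from 4101 ± 185 to 6134 ± 84.5 normalised counts with adjusted p = 2.22e-05, and SPRY4, a feedback inhibitor, fell from 3844 ± 160.3 to 2284 ± 253 with adjusted p = 4.47e-05. IER3, an immediate early gene, rose 4.89-fold and the phosphatase gene DUSP8 2.00-fold. SPRY1, related to SPRY4, and RASA1, a GTPase activator of RAS, fell 2.68-fold and 2.34-fold.

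**Figure D3:**
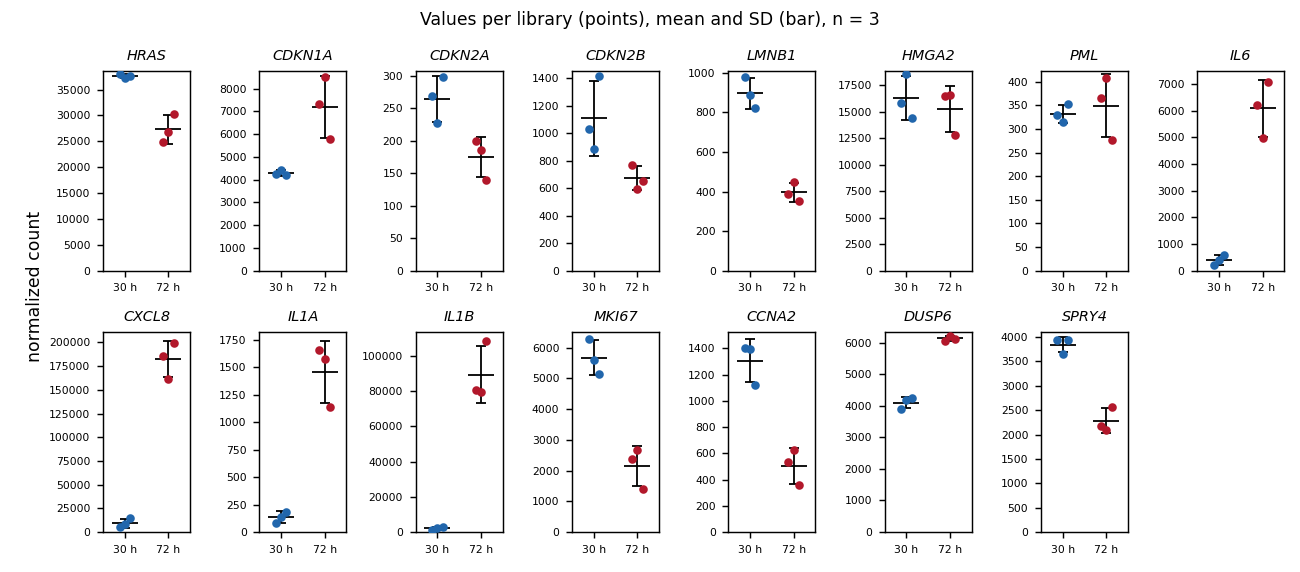
Normalised counts (y axis, from 0) of the genes reported whatever their value, with 1 point per library at 30 h (blue) and 72 h (red) and bars for mean and SD (n = 3). HMGA2 and PML overlap between the groups, while for CXCL8 the 3 libraries of 72 h, with a mean of 182123, lie above those of 30 h, with a mean of 9402.

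Interferon-stimulated genes and the targets of TGF-beta and Notch were also divided. Of 28 interferon-stimulated genes tested, 6 rose, 11 fell and 11 did not pass, the same counts as when adjusted over the list alone (camera adjusted p = 0.305). CXCL10, a T cell chemokine, rose 6.64-fold and IFIH1, a sensor of double-stranded RNA, 2.59-fold. SAMD9L and SAMD9, related antiviral genes, fell from 355 ± 46.9 to 72.0 ± 11.5 and from 267 ± 9.53 to 77.5 ± 3.77 normalised counts. Of 24 targets and components of TGF-beta and Notch signalling, 7 rose, 8 fell and 9 did not pass, the same counts as when adjusted over the list alone (camera adjusted p = 0.274). CTGF, a matricellular protein, fell from 4677 ± 523 to 772 ± 145 and HES1, a Notch target, from 253 ± 35.9 to 61.8 ± 8.35, while JAG1, a Notch ligand, rose 2.25-fold. ID3, a target of BMP and TGF-beta signalling, fell 2.34-fold with adjusted p = 0.0107, a call lost without 30 h replicate C, at adjusted p = 0.0549, and with no filter on low values, at 0.0578, the highest from 2.95e-12 over the alternatives.

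The lists of metabolism and stress also went in both directions, and none passed by camera on the limma fit. Of 37 lysosome and autophagy genes, 13 rose, 10 fell and 14 did not pass. The adjusted p of this list was 0.293, but 0.0367 with DESeq2 and 0.0193 in the authors' deposited table (0.0193 to 0.471 over the alternatives). CTSS, the gene of cathepsin S, went from 226 ± 28.2 to 2634 ± 91.8 normalised counts with adjusted p = 1.84e-08, and SQSTM1, the autophagy receptor p62, rose 2.18-fold. Of 32 genes of the unfolded protein and integrated stress responses, 9 rose, 10 fell and 13 did not pass, with 9 rising and 11 falling when adjusted over the list alone (adjusted p = 0.971). CHAC1, a glutathione-degrading enzyme, fell 6.71-fold and PHGDH, the entry enzyme of serine synthesis, 3.09-fold, while DDIT4, an inhibitor of mTOR, rose 3.70-fold and the transcription factor gene ATF3 2.51-fold. Of 31 cholesterol and fatty acid synthesis genes, 9 rose, 10 fell and 12 did not pass (adjusted p = 0.994). MVK, the mevalonate kinase, fell 2.34-fold, and FADS1, a fatty acid desaturase whose exons overlap FADS2 on the opposite strand, rose 1.73-fold. Of 21 antioxidant and NADPH oxidase genes, 10 rose, 5 fell and 6 did not pass, with 10 rising and 6 falling when adjusted over the list alone (adjusted p = 0.271). FTH1, the ferritin heavy chain, went from 11047 ± 1108 to 29753 ± 1661, while SOD3, the extracellular superoxide dismutase, fell 2.86-fold and the oxidase gene NOX4 2.05-fold. Of 40 ribosome biogenesis genes, 10 rose, 5 fell and 25 did not pass (adjusted p = 0.274), and the change was 1.44-fold for NOLC1 and 1.41-fold for RRN3, a factor of RNA polymerase I. For the lysosome, cholesterol and ribosome lists the counts were the same when adjusted over the list alone.

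Of 24 genes associated with stem cells, 10 could be tested, of which 3 rose, 6 fell and 1 did not pass, also when adjusted over the list alone. The camera adjusted p was 0.176, but 0.0107 with DESeq2, 0.00819 in the authors' deposited table and 0.0457 with no filter on low values (0.00819 to 0.229 over the alternatives). ITGA6, an integrin subunit, fell from 3950.3 ± 783 to 544 ± 125 normalised counts and NES, the intermediate filament nestin, 2.38-fold, while ALDH1A3, an aldehyde dehydrogenase, rose 1.75-fold. KLF4, a transcription factor, rose 1.82-fold with adjusted p = 0.0259, a call lost without 30 h replicate B (adjusted p = 0.0957, the highest from 0.000439 over the alternatives), 72 h replicate A (0.0641) or 72 h replicate C (0.0739).

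The median over all markers fixed was 0.461 normalised counts at 72 h for epithelial cells, 0.490 for blood cells and 13.8 for endothelial cells. Of 12 epithelial markers 1 was tested, CLDN4, a tight junction protein, which rose from 18.5 ± 6.91 to 77.5 ± 5.18 normalised counts. Of 14 blood cell markers 2 were tested, and LAPTM5, a lysosomal protein of blood cells, rose from 7.96 ± 7.63 to 66.9 ± 1.73 while CORO1A, an actin regulator named after its value was seen, fell from 37.2 ± 4.06 to 18.2 ± 7.89. The log2 fold change of LAPTM5 was 3.29 ± 0.58, 3.96 without 30 h replicate A and 2.69 without 30 h replicate B, and its call was lost without both libraries of letter C, an alternative chosen after the data were seen (adjusted p = 0.09, the highest from 2.69e-22 over the alternatives). Of 10 endothelial markers 5 were tested, of which TIE1, a receptor tyrosine kinase, rose from 18.6 ± 0.354 to 51.9 ± 16.5, EGFL7 rose from 29.1 ± 2.98 to 52.9 ± 3.56, and TEK, the angiopoietin receptor, fell from 767 ± 132 to 419.7 ± 42.4. ROBO4 and ESAM, named after their values were seen, did not pass, with 85.6 ± 3.76 and 11.5 ± 0.278 at 30 h and 104 ± 30.8 and 14.8 ± 2.58 at 72 h. The camera adjusted p was 0.204, 0.857 and 0.439 for the epithelial, blood cell and endothelial lists, and the counts of calls were the same when adjusted over each list alone.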

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

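Leaving out both libraries of letter C was chosen after the data were seen. Over the settings with another scaling, filter, pseudocount, library set or tool, 2529 to 3501 genes were higher and 2689 to 3619 lower, against 3144 and 3328. Without each library in turn the ranges were 2529 to 3174 and 2689 to 3295. With a block for the replicate letter 3271 genes were higher and 3452 lower, and 6332 of these calls were shared with the unblocked ones in the same direction. The counts were 3162 and 3331 with edgeR and 2645 and 2914 with DESeq2 on the recovered reads, 2627 and 2883 in the authors' deposited table, and 2104 and 2375 at an adjusted p under 0.01. Of the calls, 6439 of 6493 with edgeR and 5308 of 5510 in the authors' deposited table were shared with the limma calls in the same direction. A log2 fold change of at least 1 left 686 genes higher and 892 lower, by its own construction. Of the lists, 4 were higher and 4 lower. With an estimated correlation 0 were higher and 0 lower, where the estimates, up to 0.961 for the mitosis list, stand in place of 0.01. With fry, which does not compare a list with other genes, 9 were higher and 8 lower, and with no filter on low values 7 were lower, for which the cause was not tested. No scaling moved the median log2 fold change of all tested genes beyond 0.0295. Among repeats of the named genes' tests 1832 gave the same call, 13 lost it and 1 gained it (PML, without both libraries of letter C), and 0 called genes changed direction. The repeats of the lists' tests with an estimated correlation, which lost each of the 8 called lists, and with fry are not counted next. Among the other repeats of the lists' tests 373 gave the same call, 2 lost it and 16 gained it. The gains outside single libraries were those of the p53, chromatin, lysosome and stem cell lists with DESeq2 (adjusted p = 0.0458, 0.0303, 0.0367 and 0.0107) and in the authors' deposited table (0.0264, 0.00909, 0.0193 and 0.00819), of the p53, chromatin, stem cell and senescence regulator lists with no filter (0.0462, 0.00457, 0.0457 and 0.00648), and of the p53 list without both libraries of letter C (0.0449). Depth limits genes near the filter of 10 normalised counts, and folds for SERPINB4 and PI3, with 0 reads at 30 h, have no upper limit.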

Other observations

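The scans of gene families and of neighbouring genes, the value of ESR1 and the test of library scaling were chosen after the results were seen. Integrin alpha genes with a numbered symbol fell: of 10 tested, 9 fell and 0 rose, with a median log2 fold change of -1.32 (-1.32 with TMM and -1.27 with quantile scaling). ITGA8, ITGA4 and ITGA6 had log2 fold changes of -3.06, -2.92 and -2.86, while ITGA7, the member that did not pass, had 0.11. Of 27 collagen genes, 14 fell and 3 rose, with a median of -0.77 (-0.77 with TMM and -0.75 with quantile scaling). COL15A1 fell from a mean of 628 to 43.2 normalised counts and COL1A1 from 38797 to 10294.7, whereas COL7A1, the collagen of anchoring fibrils, went from 3349.6 to 6774 and COL24A1 from 63.3 to 145. The other collagen that rose, COL22A1, had a mean of 0.325 at 30 h and 25.2 at 72 h. Among 133 families of at least 10 members, camera gave both of these adjusted p = 0.00148, and adjusted p = 0.998 with an estimated correlation. Of 17 KDM genes, most of them histone lysine demethylases, 9 rose and 0 fell in each of the scalings, with a median of 0.20 and a camera adjusted p of 0.0542.

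ESR1, the gene of oestrogen receptor alpha, the receptor whose part is fused to RAS in this system, had 8026 ± 155 normalised counts at 30 h and 5800.3 ± 336 at 72 h (SD, n = 3). Its log2 fold change was -0.47 ± 0.0567 (SE) by limma with adjusted p = 0.000128, beside -0.46 ± 0.0744 for HRAS. The counts do not show which reads of either gene came from the construct.

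SERPINB4 and PI3, known from epithelia, and CTSS and TREM1, known from myeloid cells, rose at 72 h, 4 genes picked after their values were seen. The fixed epithelial and blood cell lists did not pass by camera (adjusted p = 0.204 and 0.857). Only 1 epithelial and 2 blood cell markers could be tested, so these tests say little about either list. By fry the epithelial list, through CLDN4 alone, had adjusted p = 0.00975, and the blood cell list 0.407. Epithelial cells in the 72 h cultures would bring their abundant transcripts, but the median of 12 epithelial markers at 72 h was 0.461 normalised counts, 0.24% of the 192 of SERPINB4, with KRT5 and KRT14 at 0. Of the markers detected, KRT19 had 16.5 ± 23.6 at 30 h and 12.3 ± 19.5 at 72 h (SD, n = 3) and EPCAM 7.85 and 5.14, while CLDN4 rose from 18.5 to 77.5. The median of 14 blood cell markers at 72 h was 0.490, 0.0186% of the 2634 of CTSS. This share alone decides little, because CTSS already had 226 at 30 h, when that median was 1.15. A median that did not rise, with the myeloid gene TYROBP at 0, argues against blood cells as the source of the rise in CTSS. Single markers moved both ways. LAPTM5 rose from 7.96 to 66.9 and, near the floor, PTPRC from 1.33 to 3.59 and CD68 from 2.04 to 3.91. CD14 fell from 7.52 to 4.63 and CORO1A from 37.2 to 18.2. Reads shared between SERPINB4 and SERPINB3 stay open, and no biological explanation was tested.

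Matrix and contractile genes fell at 72 h, with a list median of -1.51 on the log2 scale. The fitted trends of the fold change over transcript length and GC content ran from -0.0878 to 0.0999 (5th to 95th percentile of genes). Trends this small beside -1.51 argue against length and GC content as the whole cause. Their removal could move the median only slightly, and left it at -1.50. The camera adjusted p was then 7.17e-15 with the preset correlation, but before the correction the list had adjusted p = 0.423 with an estimated correlation. The highest median of the list under TMM or quantile scaling was -1.48. The median of all tested genes was at most 0.0295 under these scalings, so they could hardly move the list. They show a fall relative to other genes, and a change in RNA per cell was not tested. The difference in time under RAS signalling, which the design names, stays open as a biological explanation that was not tested separately.

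Genes at least 2-fold higher at 72 h lay beside each other more often than in shuffled gene orders, in 80 pairs of neighbours within 100 kb against a mean of 26.9 in 10000 shuffles. Without pairs that share a symbol stem, a stand-in for paralogs, 64 pairs remained against a mean of 25.1 (95% of shuffles from 16 to 35), and without overlapping genes 53 against 20.8 (13 to 30). With both kinds of pair left out, 40 remained against 19.5 (12 to 28). Each count had a one-sided permutation p = 1e-04, the smallest that these shuffles can give. This argues against reads shared between paralogs or overlap as the whole cause, although paralogs with other stems stay open. The longest run, of 4, was RP11-114H23.1, RPL10P13, SNORA70 and RP11-114H23.2 (chromosome 12, 75563202 to 75984015), which includes clone names. Runs of 3 included LAMB3, G0S2 and HSD11B1 (chromosome 1, 209614870 to 209734950). Another was CXCL8, CXCL6 and CXCL1 (chromosome 4, 73740506 to 73871242), which share a symbol stem. Some other runs of 3 also held clone names, and whether adjacent entries count 1 transcript was not tested. Among genes at least 2-fold lower, 93 pairs of neighbours fell together against a mean of 45.4, and no biological explanation was tested.

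The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. Each split other than the real one mixes libraries of 30 h and 72 h, which adds the time difference to its spread. Low counts of genes in those splits therefore do not measure chance. By limma 1 split, the real one, gave as many genes higher (3144) and 1 as many lower (3328), and the highest of the other splits gave 0 and 0, or 210 and 169 at an unadjusted p under 0.05 against 3601 and 3713 for the real split. For the lists, 9 splits, the real one included, gave at least as many in 1 direction as its 4 higher, and 9 as many as its 4 lower. The highest of the others gave 6. Splits with 0 genes called thus still gave list calls with the preset correlation, so the number of lists called does not set the real split apart. Those splits hold 30 h and 72 h in unequal shares, so part of the time difference remains in them. Their list calls do not measure chance either.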
